A study of Mus musculus with 4 samples.

How the data were processed

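Polyadenylated RNA of sorted fetal liver cells was sequenced in 4 libraries, 2 from the saline group and 2 from the pIC group, per the labels' protocols. The authors aligned reads with STAR 2.7.2c to mouse GRCm38 (mm10) and counted them per gene with featureCounts 1.6.3, per the submitters' processing notes, which also name DESeq2. The deposited values are raw read counts per Ensembl gene, not normalized. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The role of DESeq2 upstream is not stated, and the deposited counts are whole numbers that sum to a different total in each library. The gate of the sort is not given either.

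The table held 29168 genes, of which 193 had 0 counts in all 4 libraries. With those 193, 850 had a total under 6, while 856 had a total of 6 or 7 and 279 had 4 or 5. Any filter applied before deposit is not given in the sources used here. The numbers in the column names (saline 1 and 3, pIC 2 and 3) differ from those in the sample titles (1 and 2 in each group), so each column was given its group but no single sample, and libraries are named by the column number. Of the gene identifiers, 29121 were in GENCODE M21, 28514 with the same symbol, and coordinates came from that annotation. Where 15 symbols stood for more than 1 identifier, the one with the most counts kept the symbol.

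The design, the gene lists, the rule for naming genes and the other settings to be run were fixed before the data were examined. Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest, 2-sided, with Benjamini-Hochberg adjustment over the 18962 genes that passed the filter and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Log2 fold changes are pIC over saline throughout, and CPM are scaled by TMM, except for sums over receptor, other silent and Y-linked genes and the floors of a count, which are CPM of the library total. The TMM factors were 1.02, 1.01, 1.00 and 0.971 for saline 1, saline 3, pIC 2 and pIC 3.

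Of 29 gene lists, 28 had at least 5 members past the filter and were tested with camera (limma 3.58.1) on voom values, with a preset correlation of 0.01 and adjustment over the lists. Of the 756 symbols on the lists, 738 were in the table. The test was repeated with an estimated correlation, under which 0 lists passed (smallest adjusted p = 0.46, smallest unadjusted p = 0.0286, for erythroid genes). The fry test of a shift in 1 direction gave 0 lists past the threshold (smallest adjusted p = 0.246), and its mixed test gave 1, cell-cycle inhibitor and quiescence genes (adjusted p = 0.00118). Counts adjusted over the list alone apply the Benjamini-Hochberg method to the edgeR p-values of that list's members.

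The rule named, whatever their result, 19 fixed genes of interferon response, stem cells and lineages, and up to 4 members of each list with the smallest p among those past the threshold, or up to 2 where none passed. It also named up to 10 genes past the threshold in each direction, with both pIC libraries on 1 side of both saline libraries and a mean of at least 1 CPM in the higher group, filled up to 5 with the smallest p where fewer than 10 passed. Gene models without an approved-style symbol were passed over. The rule took 80 genes, of which 77 are reported here, and genes outside it are said to be named after their values were seen.

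No 2 libraries held the same values or differed by sampling noise alone. The chi-square statistic per degree of freedom ranged from 15.0 to 31.8 over the pairs, and Spearman's correlation across genes ranged from 0.965 to 0.972, with 0.969 between the saline libraries and 0.972 between the pIC libraries. Across all tested genes the first principal component (49.4% of the variance) set pIC 3, at 90.5, apart from the others, at -45.2, -30.7 and -14.6. Over genes with a mean of at least 5 CPM the first component (41.9%) put the saline libraries at 21.0 and 4.08 and the pIC libraries at -10.3 and -14.8. Gm26917, a locus that collects ribosomal RNA reads, took 1.59% to 1.88% of the counts.

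The test was tried on simulated counts drawn from the means and library sizes of this comparison. In each of 5 draws 200 of 18962 genes were changed 2-fold or 4-fold, and a separate list of 28 genes was shifted by 0.75. Calls of those 28 genes counted among the calls and were not counted as false. The edgeR test recovered 45% of genes changed 2-fold and 58.8% of those changed 4-fold, and 79.3% and 95.6% among genes of at least 5 CPM, with 9.41% of its calls false. DESeq2 had 12.4% of its calls false. The simulated list of 28 genes shifted by 0.75 was called in 5 of 5 draws with the preset correlation and in 0 of 5 with an estimated one. A real list that was not called with an estimated correlation is therefore not shown to be unshifted. With the preset correlation 0 of 95 unshifted lists were called. Simulated genes were drawn independently, whereas the real erythroid list had an estimated correlation of 0.271. The draws therefore cannot show how often the preset correlation calls unshifted lists whose members vary together.

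The settings run beside the main one were DESeq2's size factors or library size as scaling, no filter, a filter of at least 1 CPM in 2 libraries with a total of at least 40, each library left out in turn, DESeq2 1.42.0, limma-voom, robust fitting, a threshold of 0.1, a log2 fold change of at least 1, camera on log CPM with a prior count of 2, and the removal of sex-linked, mitochondrial and hemoglobin genes. DESeq2 was run on all 29168 genes, and 17601 had no adjusted p. Thinning of all libraries to the smallest total, a filter of at least 5 CPM in 2 libraries and edgeR's exact test were added after the data were seen. A replicate block, intended at first, was left out because the columns do not carry the numbers of the titles.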

Results

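Gene expression was measured by RNA sequencing in hematopoietic cells sorted from mouse fetal liver at E15.5, a stage at which the liver is the main site of blood formation. The source label names stem cells together with a further population that it leaves unnamed. The fetuses came from a flkswitch by wild-type cross on the C57BL/6 background, and the labels give saline as the agent for 2 samples and pIC for 2. pIC is the usual short form of polyinosinic:polycytidylic acid, a synthetic double-stranded RNA used to mimic viral infection. The table of raw counts held 29168 genes. Total counts were 13962857 in saline replicate 1, 17188208 in saline replicate 3, 30308148 in pIC replicate 2 and 31496999 in pIC replicate 3, so both pIC libraries were sequenced more deeply than both saline libraries. A count of 3 equalled 0.215, 0.175, 0.0990 and 0.0952 CPM (counts relative to library size) in that order, a floor that covers counting error alone. The labels do not say that the 2 samples of a group came from separate animals, so the p-values measure the spread between these samples. For the saline pair, Alb, a hepatocyte marker named after its values were seen, had 0.494 CPM in saline 1 and 40.3 in saline 3. Hepatocyte markers as a list had a median log2 fold change of 3.68 without saline replicate 3 and 0.10 without saline replicate 1. These values argue against the saline libraries being repeats of the same RNA. They do not show separate animals, so this spread may still be technical in part. For the pIC pair, the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, summed after their values were seen, had 2614 counts in pIC replicate 2. They had 0 counts in pIC replicate 3. These values argue against the pIC libraries being technical repeats of the same cells.

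The comparison of pIC with saline addresses how activation of the maternal immune system, named in the series title, alters fetal blood cells. Genes of the red cell lineage were higher in the pIC libraries. All 28 tested members of the erythroid list had a positive log2 fold change, with a median of 0.76 and an interquartile range of 0.53 to 0.89. Klf1, a transcription factor that switches on red cell genes, had 147 ± 17.1 CPM in saline and 269 ± 1.22 in pIC (SD, n = 2 each), a log2 fold change of 0.87 with an SE of 0.12. Gata1, a transcription factor required for red cell and platelet precursors, had 61.6 ± 5.77 and 109 ± 4.15 CPM (log2 fold change 0.82, SE 0.14), and Rhd, a blood group protein of the red cell membrane, had 85.8 ± 11.7 and 158 ± 7.42 CPM (log2 fold change 0.88, SE 0.14).

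In 26 of the 28 erythroid genes both pIC libraries lay above both saline libraries. Of all tested genes 17.4% had this arrangement, and chance gives it in 16.7% of single genes. The list members varied together (estimated correlation 0.271), so a single difference between libraries could separate most of them at once. The share for single genes is therefore no test of the list. The erythroid list rose in camera with a preset correlation of 0.01 (adjusted p = 8.46e-48), and had an adjusted p = 0.46 with an estimated correlation. With p-values adjusted over the list alone, 26 members rose in edgeR's quasi-likelihood test and 0 fell. Over all genes tested, 0 members passed in that test and 21 passed in DESeq2, each of them higher. The members outside the 26 were Nfe2 and Hbb-bt, picked out after their values were seen. Hba-a1 and Hba-a2, and likewise Hbb-bs and Hbb-bt, are near-identical gene pairs whose reads the counting could split, so their single values are uncertain. Hemoglobin genes took 0.0404% and 0.0498% of the counts in the saline libraries and 0.0827% and 0.0597% in the pIC libraries.

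**Figure D1:**
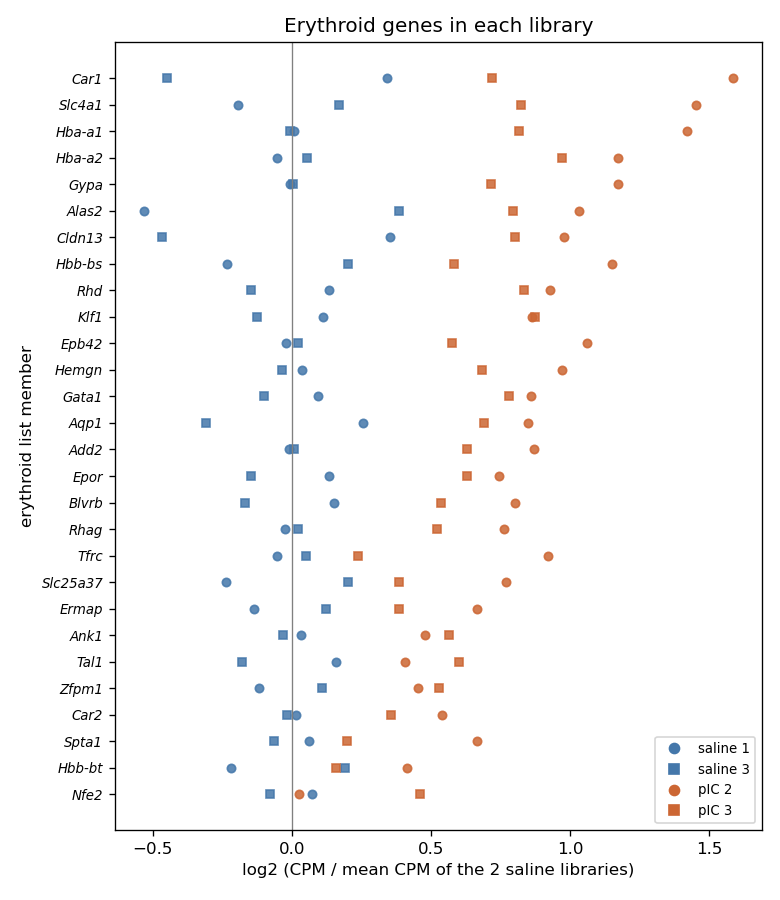
Each point is 1 library's value for 1 of the 28 tested erythroid genes. The x axis is log2 of its CPM over the mean CPM of the 2 saline libraries. Genes on the y axis are ordered by their log2 fold change in edgeR's test. In 26 of the 28 genes both pIC libraries (orange) lie to the right of both saline libraries (blue).

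Granulocyte and monocyte progenitor genes were also higher in pIC, by less. Of 29 members, 24 had a positive log2 fold change, with a median of 0.23, and the list rose in camera (adjusted p = 1.98e-07), with an adjusted p = 0.46 with an estimated correlation. Mpo, the peroxidase of neutrophil granules, had 1372 ± 22.4 CPM in saline and 2094 ± 229 in pIC (SD, n = 2 each; log2 fold change 0.61, SE 0.10). Adjusted over the list alone, 3 members rose, namely Mpo, Hp and Prtn3, of which Prtn3 was named after its value was seen, and over all genes tested 0 passed in edgeR's test, while DESeq2 called 2, Mpo and Prtn3, higher. With the filter of 1 CPM edgeR's test also called Mpo (adjusted p = 0.0319). Mature neutrophil markers, a list of cells that a sort of fetal liver could carry along, moved with this group. Their median was 0.42 over 14 members and the list rose (camera adjusted p = 0.000128), with an adjusted p = 0.53 with an estimated correlation. Adjusted over the list alone, Ngp and Fcnb rose, and Ngp, a neutrophil granule protein, had 19.1 ± 3.39 CPM in saline and 38.7 ± 1.77 in pIC (SD, n = 2 each). Without pIC replicate 3 the neutrophil list had a median of 0.11 and an adjusted p = 0.0669.

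Interferon-stimulated genes, the usual responders to double-stranded RNA, showed small differences. The 48 tested members had a median log2 fold change of 0.11, with 36 positive, and the list rose in camera (adjusted p = 0.0102), with an adjusted p = 0.62 with an estimated correlation. That call rested on pIC replicate 3, since without it the median was -0.01 and the adjusted p = 0.873, and the call was also lost without saline replicate 1 (adjusted p = 0.0552) and with a filter of at least 1 CPM (0.0537) or 5 CPM (0.0686) in 2 libraries. No member passed edgeR's test, either over all genes or adjusted over the list alone. Ifit1 had 16.8 ± 0.524 CPM in saline and 19.03 ± 0.864 in pIC (SD, n = 2 each), a log2 fold change of 0.18 with a 95% interval of -0.24 to 0.60. The log2 fold changes were 0.47 for Irf7, 0.56 for Ifi27, -0.50 for Eif2ak2 and 0.04 for Isg15. That of Isg15 changed sign after thinning, and that of Irf7 ranged from 0.18 to 0.85 over the settings run.

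Lists of other inflammatory responses gave small values. IL-6 and STAT3 response genes had a median of 0.12 over 20 members and rose in camera (adjusted p = 0.0437), with an adjusted p = 0.62 with an estimated correlation. Their median was -0.04 without pIC replicate 3 (adjusted p = 0.724), and without saline replicate 1 the adjusted p was 0.132. The call was also lost with the filters of 1 CPM (0.141) and 5 CPM (0.1005), library-size scaling (0.0611), thinning (0.0708) and camera on log CPM (0.0550). Adjusted over the list alone, Junb, a subunit of the AP-1 transcription factor, was the 1 member that rose. TNF, IL-1 and NF-kB response genes had a median of 0.08 and a mean of -0.05 over 23 members, with a direction of higher in camera and an adjusted p = 0.0565, and 0.0481 without pIC replicate 2. Their 1 member past the test adjusted over the list alone was Tnfaip2, an NF-kB target, at 77.3 ± 4.82 CPM in saline and 134 ± 11.04 in pIC (SD, n = 2 each). Antigen presentation and interferon-gamma genes had a median of -0.04 over 29 members (camera adjusted p = 0.785). Il6ra and Il1r1, receptors for IL-6 and IL-1, had log2 fold changes of 0.02 and 0.46 (edgeR adjusted p = 1.00 and 0.946). That of Il6ra changed sign under other scalings and filters, and that of Il1r1 ranged from 0.027 to 0.80 over the settings run.

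Hematopoietic stem cell genes did not pass the test. Their 34 members had a median log2 fold change of -0.06 (camera adjusted p = 0.465), and 1 member, Gfi1b, a repressor needed in red cell and platelet development, rose when p-values were adjusted over the list alone (83.3 ± 8.52 against 126 ± 1.93 CPM, SD, n = 2 each). Mecom, a transcription factor needed to maintain stem cells, had 433 ± 35.2 CPM in saline and 396 ± 10.7 in pIC, with a log2 fold change of -0.13. The stem cell surface markers Procr and Slamf1 had log2 fold changes of -0.20 and -0.19, Ly6a had 0.07, and the cell-cycle inhibitor Cdkn1c had -0.23. Cd34 had 0.12 and the stem cell factor receptor gene Kit had 0.09, which became -0.03 without saline replicate 1.

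Among other lineage lists, multipotent progenitor and lymphoid-priming genes had a median of 0.06 over 30 members (camera adjusted p = 0.167). Flt3, the receptor of multipotent progenitors, had 87.4 ± 26.5 CPM in saline and 127 ± 20.8 in pIC (SD, n = 2 each), and Il7r, the receptor of lymphoid precursors, had 1.80 ± 0.256 and 0.725 ± 0.562 CPM. Megakaryocyte genes had a median of 0.16 over 22 members (adjusted p = 0.491). With each library left out it ranged from -0.17 without pIC replicate 2 to 0.50 without saline replicate 1. Fetal-type hematopoietic genes had a median of 0.15 over 15 members (adjusted p = 0.122). Mast cell and basophil genes had a median of 0.13 and a mean of -0.00 over 13 members (adjusted p = 0.0995). The last 3 lists each passed the threshold without 1 of the libraries: megakaryocyte genes without pIC replicate 3 (adjusted p = 1.54e-07), fetal-type genes without saline replicate 3 (adjusted p = 0.00462), and mast cell genes without saline replicate 1 (adjusted p = 0.00836) or pIC replicate 3 (adjusted p = 0.0027). With all 4 libraries the mast cell list also passed with the filters of 1 CPM (adjusted p = 0.0232) and 5 CPM (0.0396), after thinning (0.0178) and without a filter (0.0334), and the fetal-type list passed without a filter (0.0117).

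Genes of cell division and of the early stress response were slightly higher in pIC. The 39 G2 and M-phase genes had a median of 0.11, with 32 positive (camera adjusted p = 5.56e-06, and adjusted p = 0.46 with an estimated correlation), and 0 members passed adjusted over the list alone. Their median was 0.22 without saline replicate 1, and 0.10 to 0.15 without another library. Plk1, a mitotic kinase, had 129 ± 5.53 CPM in saline and 166 ± 0.323 in pIC (SD, n = 2 each), and Mki67, a marker of cycling cells, had 253 ± 4.65 and 297 ± 10.7 CPM. The 23 immediate-early and heat-shock genes had a median of 0.26 (camera adjusted p = 5.56e-06, and adjusted p = 0.46 with an estimated correlation). Junb, Hspa8, Jun and Btg2 rose adjusted over the list alone, of which Jun was named after its value was seen, and Hspa8, a constitutive chaperone, had 2249 ± 284 CPM in saline and 2907 ± 33.3 in pIC (SD, n = 2 each).

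Further lists of growth and stress passed the same test and did not pass with an estimated correlation. A simulated shifted list was not called in that setting either, so it cannot decide whether these lists moved. Their estimated correlations were -0.0256 for unfolded protein response, -0.00296 for S-phase, -0.00719 for p53 target and -0.0216 for ribosome biogenesis genes. All lay below the preset 0.01, so members varying together did not cost these calls. Unfolded protein response genes had a median of 0.10 over 24 members (camera adjusted p = 0.00883, and adjusted p = 0.46 with an estimated correlation), with Asns, the asparagine synthetase gene, the 1 member that rose adjusted over the list alone. S-phase genes had a median of 0.08 over 40 members (adjusted p = 0.0138, and adjusted p = 0.46 with an estimated correlation), p53 target genes 0.20 over 23 (adjusted p = 0.0147, and adjusted p = 0.46 with an estimated correlation), and ribosome biogenesis and Myc target genes 0.08 over 35 (adjusted p = 0.0319, and adjusted p = 0.46 with an estimated correlation). Without pIC replicate 2 the adjusted p was 0.164 for S-phase genes, 0.0702 for p53 target genes and 0.136 for ribosome biogenesis genes. Without saline replicate 1 it was 0.109 for p53 target genes, whose median was then 0.07, and 0.08 after thinning, and without pIC replicate 3 it was 0.103 for ribosome biogenesis genes. With the filters of 1 and 5 CPM the call was lost for unfolded protein response genes (adjusted p = 0.0531 and 0.101), S-phase genes (0.127 and 0.376), p53 target genes (0.0537 and 0.208) and ribosome biogenesis genes (0.178 and 0.517). S-phase and ribosome biogenesis genes also lost it with library-size scaling (0.0611 and 0.114) and thinning (0.0646 and 0.114). Cell-cycle inhibitor and quiescence genes had a median of 0.05 over 26 members (adjusted p = 0.145), and Cdkn2c, a cyclin-dependent kinase inhibitor, rose adjusted over the list alone from 4.22 ± 0.477 to 10.6 ± 0.123 CPM (SD, n = 2 each).

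Mitochondrially encoded genes were the 1 list that fell. Their 13 members had a median of -0.19 (camera adjusted p = 0.0129, and adjusted p = 0.62 with an estimated correlation), and mt-Co1 had 3350 ± 378 CPM in saline and 2931 ± 340 in pIC (SD, n = 2 each). The call rested on saline replicate 1, without which the median was -0.02 (adjusted p = 0.919), and without pIC replicate 3 the adjusted p was 0.103. Oxidative phosphorylation genes encoded in the nucleus had a median of -0.00 and a mean of -0.01 over 40 members, with a direction of higher in camera (adjusted p = 0.647). Cytosolic ribosomal protein genes had a median of 0.05 over 36 members (adjusted p = 0.0522). Both of these lists changed direction with the library left out. Without saline replicate 1 they were higher in pIC (adjusted p = 0.000735 and 1.38e-12), and without saline replicate 3 they were lower (adjusted p = 0.0322 and 0.00908). Ribosomal protein genes were also higher without pIC replicate 3 (median 0.11, adjusted p = 0.00174). Glycolysis genes had a median of -0.07 over 22 members (adjusted p = 0.380, and 0.0306 without pIC replicate 3), and cholesterol biosynthesis genes -0.07 over 25 (adjusted p = 0.647).

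**Figure D2:**
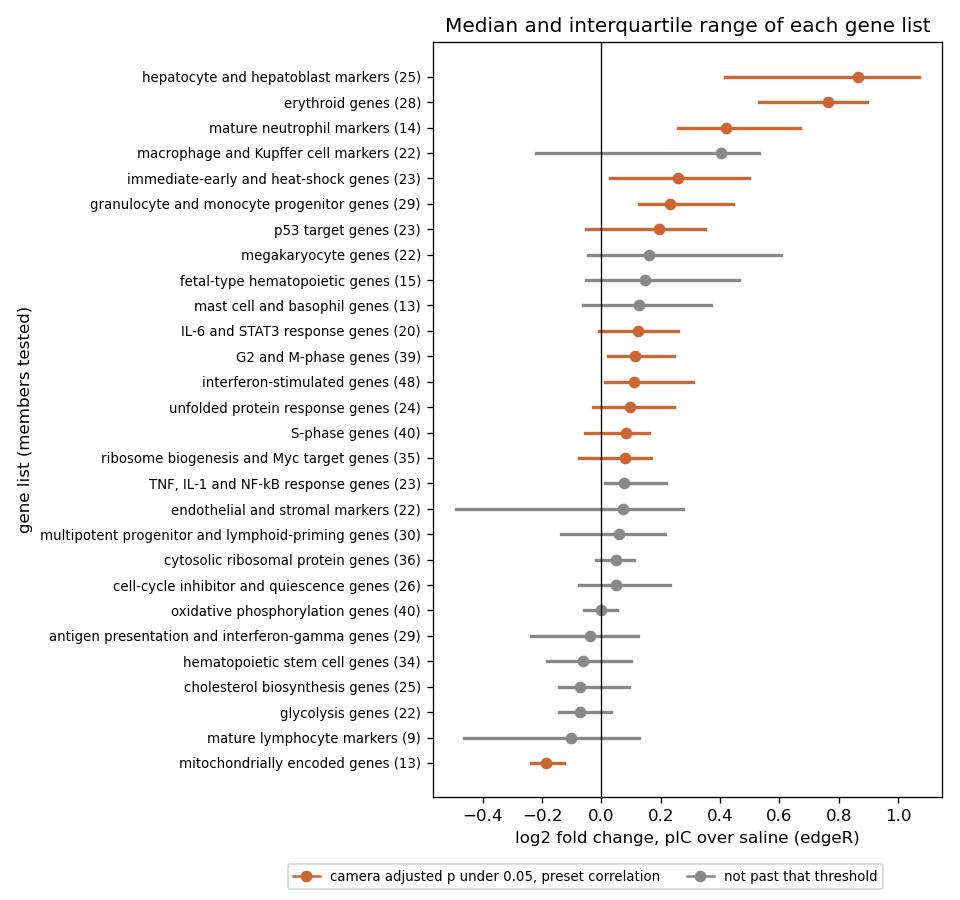
Points are the median log2 fold change, pIC over saline (x axis), of each of the 28 tested gene lists, named on the y axis with the number of tested members, and lines span the interquartile range over genes. Orange lists had a camera adjusted p under 0.05 with the preset correlation (12 higher, 1 lower), and 0 lists did with an estimated correlation.

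Markers of other cells differed between single libraries. Hepatocyte and hepatoblast markers had a median log2 fold change of 0.87 over 25 members (camera adjusted p = 3.62e-07, and adjusted p = 0.58 with an estimated correlation), which rested on saline replicate 1. Albumin (Alb) was named after its values were seen. It had 0.494 CPM in saline 1, 40.3 in saline 3, 57.7 in pIC 2 and 23.01 in pIC 3. Trf, which the rule named, differed less, with 53.6, 123, 182 and 105 CPM in that order. Without saline replicate 1 the list had a median of 0.10 and an adjusted p = 0.978. Macrophage and Kupffer cell markers had a median of 0.40 over 22 members (adjusted p = 0.192). Without pIC replicate 2 the median was 0.12 (adjusted p = 0.0348), without pIC replicate 3 it was -0.11 (adjusted p = 0.968), and with the filter of 5 CPM, which left 8 members, it was 0.12. Endothelial and stromal markers had a median of 0.07 over 22 members, with a direction of lower in camera (adjusted p = 0.927). Mature lymphocyte markers had a median of -0.10 and a mean of -0.88 over 9 members (adjusted p = 0.647), and the mean includes a fitted value for Il2rb, which had 0.705 ± 0.10 CPM in saline (SD, n = 2) and 0 counts in pIC. The median is the same with Il2rb set to its floor. Of the sex-linked list, too small to test as a group, Xist fell adjusted over the list alone, from 208 ± 3.99 to 153 ± 2.20 CPM (SD, n = 2 each), while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had counts in pIC replicate 2 only. Xist overlaps Tsix on the other strand, and its value is uncertain because the strand setting of the counting is not given.

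**Figure D3:**
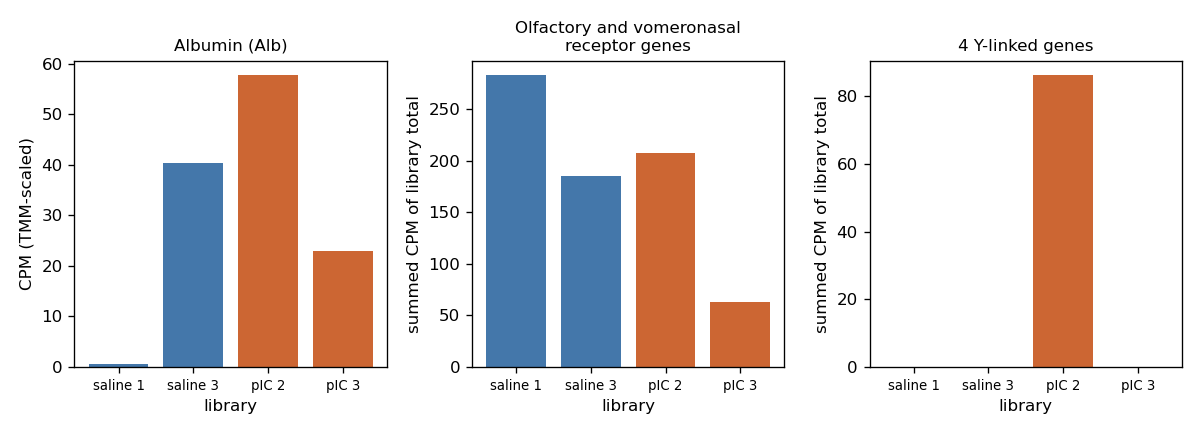
Bars give 1 value per library, in CPM from 0, for albumin (scaled by TMM), for the sum over 822 olfactory and vomeronasal receptor genes, and for the sum over 4 Y-linked genes (both sums as CPM of the library total). Albumin, picked after its values were seen, is near 0 in saline replicate 1. The receptor sum is 63.0 in pIC replicate 3 against 185 to 283 in the others. The Y-linked sum is above 0 in pIC replicate 2 alone, at 86.2.

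Gene by gene, edgeR's quasi-likelihood test called 0 of 18962 genes at an adjusted p under 0.05, with 1264 genes under an unadjusted p of 0.05 where chance gives 948. DESeq2 called 86 genes, 82 higher and 4 lower in pIC, and limma-voom called 4, all higher. With a filter of at least 1 CPM in 2 libraries, edgeR's test called 20 genes, all higher, each of them also a DESeq2 call, and 8 of them members of the erythroid list. With its usual filter the test called 0 without saline replicate 1 and 0 without saline replicate 3. Without pIC replicate 2 it called 257 genes (85 higher, 172 lower) and without pIC replicate 3 it called 109 (85 higher, 24 lower), where the lone pIC library was assumed to vary like the saline libraries. Without pIC replicate 2 the lone pIC library was pIC replicate 3, which had 23293 genes detected against 25964 to 26772 in the others. Its counts in olfactory and vomeronasal receptor genes were also low. The lower calls in that setting cannot be separated from these features of that library. Of the 82 genes that DESeq2 called higher, Ddx3y, Kdm5d and Eif2s3y had counts in pIC replicate 2 only.

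The 5 genes with the smallest p among those higher in pIC included Klf1 and Rhd of the erythroid list, both with an edgeR adjusted p = 0.164. Cited4, a transcriptional co-regulator, had 65.5 ± 5.95 CPM in saline and 137 ± 6.05 in pIC (SD, n = 2 each), a log2 fold change of 1.06 with an SE of 0.13 (edgeR adjusted p = 0.143, DESeq2 adjusted p = 4.96e-10). Abcb10, a mitochondrial transporter used in heme production, had 107 ± 6.62 and 225 ± 35.1 CPM, a log2 fold change of 1.08 with an SE of 0.14 (edgeR adjusted p = 0.143, DESeq2 adjusted p = 7.41e-11). Fech, ferrochelatase, which puts iron into heme, had 194 ± 4.37 and 334 ± 23.7 CPM, a log2 fold change of 0.79 with an SE of 0.11 (edgeR adjusted p = 0.164, DESeq2 adjusted p = 5.44e-09).

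The 5 genes with the smallest p among those lower in pIC were on none of the fixed lists. Mylk, myosin light chain kinase, had 12.9 ± 1.30 CPM in saline and 4.96 ± 0.203 in pIC (SD, n = 2 each), a log2 fold change of -1.38 with an SE of 0.25 (edgeR adjusted p = 0.225, DESeq2 adjusted p = 0.027). Mpdz, a scaffold protein with many PDZ domains, had 57.4 ± 8.93 and 33.8 ± 3.78 CPM, a log2 fold change of -0.76 (DESeq2 adjusted p = 0.022). Dennd5b, Mroh2a and Zfp329 had log2 fold changes of -1.41, -1.09 and -0.87 and passed neither test. The other genes that DESeq2 called lower were Xist and Arrdc3, the latter named after its value was seen.

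On GRCm38, with the GENCODE M21 annotation, Cited4 (ENSMUSG00000070803) lies on the plus strand of chromosome 4 from 120666572 to 120667820 and Rhd (ENSMUSG00000028825) on the same strand from 134864536 to 134896172. Abcb10 (ENSMUSG00000031974) lies on the minus strand of chromosome 8 from 123952459 to 123983122, Klf1 (ENSMUSG00000054191) on its plus strand from 84901928 to 84905291, and Fech (ENSMUSG00000024588) on the minus strand of chromosome 18 from 64452914 to 64490251. Mpo (ENSMUSG00000009350) lies on the plus strand of chromosome 11 from 87793581 to 87804413, and Gata1 (ENSMUSG00000031162) on the minus strand of chromosome X from 7959260 to 7978071. Mylk (ENSMUSG00000022836) lies on the plus strand of chromosome 16 from 34745210 to 35002420 and Mpdz (ENSMUSG00000028402) on the minus strand of chromosome 4 from 81278500 to 81442815. All of these are protein-coding genes and each value counts the whole gene. Abcb10 overlaps Gm45890, Mpo overlaps Gm11505, and Mylk overlaps E130310I04Rik and Gm21691, so their counts are uncertain where reads could not be told apart by strand.

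Both pIC libraries were deeper than both saline libraries, and the erythroid list kept a median of 0.76 after all libraries were thinned to the smallest. With 2 libraries per group the biological coefficient of variation was 25.9% over all tested genes and 13.4% over the 10945 with a mean of at least 5 CPM.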

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

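The sum over 4 Y-linked genes was a test chosen only after the result was seen. Ddx3y, Uty, Kdm5d and Eif2s3y together had 86.2 CPM of the library total (2614 counts) in pIC replicate 2 and 0 counts in the other 3 libraries, where a count of 0 allows up to 0.215 CPM in saline replicate 1, 0.175 in saline replicate 3 and 0.0952 in pIC replicate 3. The genes stood out because they had counts in a single library and 0 in the control libraries. They did not pass the filter of the edgeR test, while DESeq2, run without it, called Ddx3y, Kdm5d and Eif2s3y higher in pIC. Xist, which is transcribed from an inactive X chromosome, had 205, 211, 154 and 151 CPM, scaled by TMM, in saline 1, saline 3, pIC 2 and pIC 3. RNA of male cells was thus detected in pIC replicate 2 alone, and the DESeq2 calls of Ddx3y, Kdm5d and Eif2s3y rest on that library. Treatment alone does not account for these calls, since pIC replicate 3, of the same group, had 0 counts of the 4 genes. The labels give no sex for the fetuses and do not say how many were pooled. No biological explanation of the difference between libraries was tested.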

How the results depend on the processing

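The tests on thinned counts, with a filter of 5 CPM and with edgeR's exact test, and the count of separated erythroid genes, were chosen only after the result was seen. No paired analysis was possible because the columns carry numbers that differ from the titles and of which the groups share only 1. The genes called depended on filter and tool. Against 0 in edgeR's quasi-likelihood test, 157 genes were called without a filter (113 higher, 44 lower), 20 with the filter of 1 CPM (20 higher), 52 with that of 5 CPM (44 higher, 8 lower), 86 by DESeq2 (82 higher, 4 lower), 4 by limma-voom (4 higher), 68 by the exact test (60 higher, 8 lower) and 2 after thinning (2 higher). Leaving out each library gave 0 to 257 calls, with 0 to 85 higher and 0 to 172 lower. Both fewer and more genes tested gave more calls, and the cause was not tested.

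Of the lists, 12 were higher in pIC, against 17 without a filter (with TNF, fetal-type, mast cell, quiescence and cytosolic ribosomal protein genes added), 7 with either filter of 1 or 5 CPM and 0 with an estimated correlation. The 1 lower list became 0 without sex-linked, mitochondrial and hemoglobin genes, since its members are then removed, 0 with an estimated correlation, and 0 to 3 when each library was left out. The lists of erythroid, granulocyte and monocyte progenitor, G2 and M-phase, and immediate-early and heat-shock genes did not pass the fry test of 1 direction. Their adjusted p in that test was 0.261, 0.330, 0.323 and 0.330. In camera these lists passed in every setting run except the estimated correlation. For erythroid genes the adjusted p ranged from 7.97e-98 to 1.58e-35 and became 0.46 with an estimated correlation, and 27 members had the groups apart without each library, against 26, where 3 libraries set an easier criterion than 4.

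Of 77 named genes, 74 kept their direction wherever they were tested, and of 28 lists, 17 kept that of camera. Of those 17, medians changed sign for interferon-stimulated genes (-0.011) and macrophage markers (-0.11) without pIC replicate 3, and for quiescence genes with the filter of 5 CPM (-0.0091) and after thinning (-0.0060). The median log2 fold change of all genes was -0.01, and -0.05 with library-size scaling. The directions below reversed in the settings named, and the cause was not tested. Without a filter the adjusted p was 0.925 for antigen presentation genes, 0.986 for stem cell genes, 0.925 for cholesterol genes and 0.971 for endothelial markers. For endothelial markers it was 0.965 with library-size scaling and 0.927 on log CPM. For oxidative phosphorylation genes it was 0.863 with the filter of 1 CPM and 0.569 with that of 5 CPM. For mature lymphocyte markers it was 0.565 with the filter of 1 CPM and 0.699 after thinning. The log2 fold change of Isg15 was -0.041 after thinning, and that of Il6ra was -0.016, -0.053 and -0.015 with library-size scaling, thinning and the filter of 5 CPM.

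Leaving out each library in turn gave both directions for 11 lists. The adjusted p ranged from 0.144 to 0.615 for antigen presentation genes, 0.000211 to 0.724 for IL-6 genes, 0.103 to 0.850 for stem cell genes, 1.54e-07 to 0.547 for megakaryocyte genes, 1.38e-12 to 0.925 for ribosomal protein genes, 0.000735 to 0.8785 for oxidative phosphorylation genes, 0.0306 to 0.697 for glycolysis genes, 0.0564 to 0.8785 for cholesterol genes, 2.10e-53 to 0.978 for hepatocyte markers, 0.185 to 0.850 for endothelial markers and 0.443 to 0.774 for lymphocyte markers. The log2 fold change ranged from -0.026 to 0.22 for Kit, -0.18 to 0.24 for Isg15 and -0.12 to 0.19 for Il6ra. The simulation, in which depth was not varied, recovered 45% of 2-fold changes over all genes and 79.3% at 5 CPM or more.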

Other observations

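The tests chosen only after the result was seen were those of hemoglobin genes, carry-over, single libraries, other splits of the libraries, the depth and treatment effects on receptor genes, the treatment effect on hepatocyte markers, and thinning as a setting.

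Heme synthesis enzymes outside the fixed lists are given as single values. They were chosen after the erythroid genes and Fech were seen, so a median taken over them was dropped as a test. Of the 6 genes Alad, Uros, Urod, Cpox, Ppox and Fech, DESeq2 called 4 higher and edgeR's quasi-likelihood test called 0. Cpox had 330 ± 6.62 CPM in saline and 539 ± 85.6 in pIC (SD, n = 2 each), a log2 fold change of 0.71 with an SE of 0.13 (edgeR adjusted p = 0.201, DESeq2 adjusted p = 6.01e-06). Urod had 145 ± 14.8 and 191 ± 0.80 CPM, a log2 fold change of 0.41 with an SE of 0.12 (edgeR adjusted p = 0.562, DESeq2 adjusted p = 0.101).

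The higher erythroid genes kept a median of 0.76 after thinning all libraries to the smallest total and 0.72 without the hemoglobin genes. The median was at least 0.62 without any 1 library. Hemoglobin RNA and a single library thus did not carry the median alone. Dropping hemoglobin genes could hardly lower it much, since all 28 tested members were higher, with a lower quartile of 0.53. Thinning keeps the expected CPM ratio of well-counted genes, so it cannot exclude other effects of depth. Carry-over of hemoglobin-rich red cell precursors would add hemoglobin above all. The 5 tested hemoglobin genes, 4 on the list and Hbb-bh1, gained 0.159 of what the other 24 list members gained (0.0825 to 0.214 over the pairings of a pIC with a saline library), which is under the bound written for excluding carry-over. It was labelled open after the value was seen, since reads shared by the near-identical gene pairs may have been dropped in counting. A larger share of early erythroid progenitors within the sorted cells, or a shift of progenitors toward that program under maternal pIC, may account for the pattern and was not tested. Of the 3 splits of the 4 libraries into pairs, the real one gave 1264 genes at an unadjusted p under 0.05 and the highest other 632, and in DESeq2 86 calls and 7. The real split was the 1 with the most genes by both tools, and 3 splits are too few for a share under 0.05. It is also the split that parts the deeper libraries from the shallower ones, so its rank cannot tell treatment from depth.

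Counts in genes silent in blood cells were low in pIC replicate 3. The 822 olfactory and vomeronasal receptor genes summed to 283 CPM of the library total in saline 1, 185 in saline 3, 207 in pIC 2 and 63.02 in pIC 3. Depth does not account for this, since pIC 2, of similar depth, had 3.285 times the sum of pIC 3, nor does treatment alone, since pIC 2 had 0.885 of the saline mean. Genomic or unspliced background that differs between libraries may account for it, as other silent families in pIC 3 had 0.410 of the mean of the other libraries, although single families ranged from 0.0943 to 1.20. The match of gene names was corrected after that value was seen, because it had taken in Crybg genes, which are expressed, and with them the ratio was 0.675, above the bound of 0.67 set beforehand.

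Hepatocyte markers were nearly missing from saline replicate 1. Afp, named after its values were seen, had 2.40 CPM there against 127, 213 and 79.0 in saline 3, pIC 2 and pIC 3. Treatment alone does not account for this, since saline 3 lay within the range of the pIC libraries for Afp, and for Alb (40.3 against 57.7 and 23.01 CPM). Without saline 1 the list had a median of 0.10, but removing the library that defines the pattern could hardly leave it high. Carry-over of hepatocyte RNA into the other 3 libraries may be the source and stays open. Counts of 24 markers correlated between each pair of them with a Spearman coefficient of at least 0.9345 across genes, which is above the bound written for a shared source. It was labelled open after the value was seen, since any pair of the 4 libraries reached 0.965 to 0.972 over all tested genes. Of the 25 tested markers 1, Dlk1, was also on the fetal-type list, and Trf had 53.6 CPM in saline 1. The sort should remove hepatocytes, its gate is not given, and no biological explanation other than treatment was tested.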
